A study of Arabidopsis thaliana with 8 samples.

How the data were processed

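RNA of whole 7-day-old Arabidopsis seedlings was measured on 8 Affymetrix arrays, 2 each of Ws, Ler, a de-etiolated mutant (Col) and a gibberellin-deficient mutant (Ler). The table holds 1 signal intensity per probe set and array, as deposited by the authors. The values were made with MAS5, per the submitters' processing notes. Further settings of that step are not stated. The 2%-trimmed mean of 100.01 in each array shows that the arrays had been scaled to a common level. Each column was matched to its sample by its identifier, and the group was taken from the labels.

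The table holds 22810 probe sets, of which 64 are array controls. Names came from the array's annotation table alone. It names 1 gene for 13513 probe sets, 1580 of them with a symbol other than the locus tag, several genes for 503, and none for 8730, which are unnamed here. Of the 1-gene probe sets, 13436 were matched to a locus tag of the gene table (assembly TAIR10.1), which was used for names and gene order only.

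Signals were used as log2(signal + 2.96), the pseudocount being 10% of the median signal of 29.6 of probe sets that name a gene. A fold change on this scale understates the change of dim genes. The lowest 40% of probe sets by mean log2 value and the controls were left out, and 13648 were tested. All 4 groups entered 1 limma fit (lmFit, contrasts.fit and eBayes with a mean-variance trend) with 4 residual degrees of freedom and about 8.00 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The median SE was 0.197 for a difference of 2 groups and 0.171 against the mean of both wild types. The number of arrays limits the precision. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so p-values measure the spread between these samples only.

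The gibberellin-deficient mutant was compared with Ler, the de-etiolated mutant with the mean of Ws and Ler and with each of them, and Ws with Ler. The comparisons, tests, gene lists and alternatives were set before the data were examined. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, for lists with at least 4 measured members. Of 335 genes in 27 such lists, 49 were named alone by a probe set and 38 were tested, so 25 lists did not reach 4 members. Only expansins and xyloglucan endotransglucosylases could be tested. A further 22 lists were written from symbols after the annotation was read and before any contrast was seen, and 21 of them could be tested. Where a gene had several probe sets, that with the highest mean stood for it in a list.

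The genes named were the members of the mutants' own hormone lists, and for each comparison the 8 largest rises and 8 largest falls among called probe sets that name 1 gene with a symbol and whose arrays do not overlap between groups. Up to 4 called members of each list with a camera call or at least 2 called members were named, and the label check genes. Since few probe sets carry a symbol, the rule of 8 was also applied to genes known by locus tag only, after the annotation was read. EXO, XTH26, AT5MAT, UGT72B3, SPY, SLY1, EXPA8 in the gibberellin-deficient mutant and the plastid classes were named after their values were seen.

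Runs of neighbouring genes were sought in windows of 15 measured genes along each chromosome, with 1000 shuffles of the gene order setting the limit, a search added after the data were seen. Alternatives covered the normalization, the pseudocount, the filter, the trend, the samples in the fit, the threshold, cross-hybridising probe sets, the control group, the set test, a replicate block and leaving out each array in turn.

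The steps were tested on simulated data for 13648 probe sets with 200 changed. Of 100 probe sets changed 2-fold, 80 were recovered for the gibberellin-deficient mutant against Ler, 88 for the de-etiolated mutant against both wild types and 77 for Ws against Ler. All 100 changed 4-fold were recovered in each, with 17, 14 and 13 false calls, and a planted run of 30 genes was found in each with 0 windows elsewhere. The simulated noise was independent for each probe set, so this does not show how the search behaves where neighbouring genes vary together. R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, were used.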

Results

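Transcript levels were measured in 7-day-old Arabidopsis seedlings on 8 arrays, which fell into 4 groups of 2 arrays each. The groups were the wild types Ws and Ler, a de-etiolated mutant in the Col background, and a gibberellin-deficient mutant in the Ler background whose allele is leaky. De-etiolated mutants grow in the dark as if they were in light, and gibberellins are hormones that promote stem growth and germination. The labels named neither mutated gene, and no Col wild type was among the samples. The 2%-trimmed mean signal was 100.01 in all 8 arrays to within rounding, and the median signal ranged from 34.9 to 38.4. Correlations of log2 signal across probe sets were 0.973 to 0.978 within groups and 0.908 to 0.966 between arrays of different groups. The ratio of 3′ to 5′ signal of the older actin control was 5.22 and 4.77 in Ler and 3.84 and 4.93 in the gibberellin-deficient mutant. It was 1.90 to 2.35 in Ws and the de-etiolated mutant, while the newer actin control lay between 1.16 and 1.5 in all arrays. The ubiquitin ratio was 1.83 and 1.44 in Ws, 0.986 and 1.65 in the de-etiolated mutant, 0.943 and 0.790 in Ler, and 0.989 and 0.929 in the gibberellin-deficient mutant. The 25S rRNA control signal was 108 and 62.4 in the de-etiolated mutant and 69.7 and 39.6 in the gibberellin-deficient mutant, against 22.2 to 32.0 in the 4 wild-type arrays. Below, a change is a log2 difference of group means with its limma standard error (SE) where given, p-values are adjusted for all probe sets tested, and signals are means ± SD of 2 arrays.

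The comparison of the gibberellin-deficient mutant with Ler asked which transcripts differ when gibberellin synthesis is impaired, against the wild type of the same background. In the mutant, transcripts of 6 of 26 measured wall-modifying proteins rose and 1 fell, while 4 of 7 CYP71B cytochromes P450 fell. Of 13 plastid-encoded ribosomal proteins, a class formed after the values were seen, 6 fell. The list calls of wall proteins, plastid-encoded genes and CYP71B genes were lost with an estimated correlation (adjusted p = 0.36, 0.68 and 0.35). Signal of the xyloglucan-modifying enzyme XTH19 rose from 121 ± 17.2 in Ler to 281.5 ± 3.36 in the mutant, a log2 change of 1.2 (SE 0.21). Signal of rpl22, a protein of the large plastid ribosomal subunit, went from 1328 ± 123 to 297.5 ± 58.9, a log2 change of -2.16 (SE 0.15, adjusted p = 1.18e-05). In all, 1464 of 13648 probe sets changed, 621 higher and 843 lower in the mutant, and 498 of them changed at least 2-fold (171 higher and 327 lower). Of the probe sets also called between Ws and Ler, 59 were higher in both the mutant and Ws, where independent lists would give 16.8. A further 113 were lower in both (26.2) and 47 went opposite ways (42.1). Both comparisons share the Ler arrays, so part of the changes may reflect the Ler samples and not the mutation. The 25S rRNA control was higher in both arrays of this mutant than in both of Ler.

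Among genes with a symbol, the largest rises were in UGT71C1, a glycosyltransferase (1.34), AN, which shapes leaf cells (1.33), the cysteine protease CP1 (1.31) and IRX15-L, which acts in xylan synthesis (1.22). MYBC1 (1.21), XTH19 (1.2), the transcription factor tny (1.15) and SIM, an inhibitor of cyclin-dependent kinases (1.14), followed. The largest falls were in the ubiquitin ligase RING1 (-2.62), the carboxypeptidase scpl46 (-2.58) and CYP71B23 (-2.55). The plastid genes rpl22 and rpl14 (-2.15), the phosphatase SAL2 (-2.13), ECS1 (-2.05) and the pectin methylesterase ATPMEPCRB (-1.85) also fell. Among genes known only by a locus tag, AT2G15560 rose most (3.92), with a signal of 8.0 ± 5.77 in Ler, 151 ± 0.917 in the mutant and 200.01 ± 24.9 in Ws. AT5G10040 (2.25), AT4G39675 (2.22), AT2G47780 (2.06), AT1G33790 (1.89), AT3G11930 (1.82), AT1G33055 (1.79) and AT2G17850 (1.78) rose as well. AT5G43450 (-4.67) and AT1G65500 (-4.63) fell most, ahead of AT1G70810 (-3.77), AT1G43910 (-3.77), AT1G69730 (-3.28), AT5G24210 (-3.26), AT2G43620 (-3.09) and AT2G41090 (-2.95). With a pseudocount of 50% of the median signal the changes of AT2G15560 (2.89), AT5G43450 (-3.15), AT1G65500 (-3.98), AT1G70810 (-2.57), AT1G69730 (-2.45), AT5G24210 (-2.50) and scpl46 (-1.59) were smaller. AT1G65500 (-3.09), ECS1 (-2.81) and AT2G15560 (4.31) differed from Ler in the same direction in Ws, a wild type. Signal of AT5G10040 was 87.3 and 30.3 in the Ler arrays, against 310 and 214 in the mutant. Calls were lost on leaving out single arrays of either group for CP1 (adjusted p up to 0.13), MYBC1 (0.25), SIM (0.068), AT5G10040 (0.10), AT1G33055 (0.15) and AT2G17850 (0.17), and without replicate 1 of the mutant for AT1G70810 (0.053).

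Expansins, which loosen the cell wall, were shifted upward in the mutant (camera, adjusted p = 0.00023). With an estimated correlation between genes this was not called (adjusted p = 0.13). Of 9 measured expansins, 3 rose, EXPA20 (1.13), EXPB3 (0.94) and EXPA9 (0.78), and 6 passed when adjusted over the list alone. Xyloglucan endotransglucosylases were not shifted as a list (camera, adjusted p = 0.19). Of its 7 measured members XTH19 and XTH32 (1.0) rose and XTH33 (-0.79) fell. The gibberellin receptors GID1A (0.44, adjusted p = 0.11), GID1B (0.55, adjusted p = 0.21) and GID1C (0.34, adjusted p = 0.47) did not pass the test. No other gene of gibberellin synthesis, feedback or inactivation in the lists fixed beforehand was named by a probe set. An added list of 6 measured gibberellin-related genes, which holds the 3 receptors, had a median of 0.39 and was not called (camera, adjusted p = 0.054, and 0.61 with an estimated correlation). Of its members XERICO rose (0.93), and SPY (0.32, adjusted p = 0.24) and SLY1 (-0.09, adjusted p = 0.80) did not pass the test. XERICO lost its call without replicate 2 of the mutant (adjusted p = 0.059). GASA9 of the gibberellin-responsive GASA family had a log2 change of -0.90 (adjusted p = 0.055), which passed without replicate 1 of the mutant (0.018). BCAT4, of methionine-derived glucosinolate synthesis, fell (-0.78), with its call lost without Ler replicate 1 or either mutant array (adjusted p up to 0.17), and AOP3 of the same pathway had a change of -1.27 (adjusted p = 0.075). AOP3 passed without Ws replicate 1 (adjusted p = 0.0029) or Ws replicate 2 (0.0036). The calls of EXPA9 (adjusted p = 0.12) and EXPB3 (0.19) were lost without Ler replicate 1 or either mutant array, and that of XTH33 without either Ler array or replicate 1 of the mutant (0.26).

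Further lists, written after the annotation was read and before any contrast was seen, gave 4 camera calls with the preset correlation. Wall-loosening and wall-modifying proteins, which hold the expansins too, were shifted upward (adjusted p = 0.0088), with 6 of 26 measured members higher and 1 lower. Cold, dehydration and late embryogenesis genes were shifted upward (adjusted p = 0.0088), with XERICO (0.93) and COR47 (0.60) higher of 7. CYP71B cytochromes P450 were shifted downward (adjusted p = 0.011), with CYP71B23, CYP71B26 (-1.19), CYP71B34 (-0.77) and CYP71B6 (-0.72) lower of 7. Plastid-encoded genes were shifted downward (adjusted p = 0.0499), with 13 of 66 lower and 1 higher. None of these lists was called with an estimated correlation, with adjusted p = 0.36 for the wall proteins, 0.35 for the cold and dehydration genes, 0.35 for the P450s and 0.68 for the plastid genes. Other members of added families changed singly, among them the glycosyltransferase UGT87A2 (-1.5), the wall-acetylation proteins TBL25 (1.07), TBL39 (1.02) and TBL37 (-0.87), the tubulins TUB1 (0.78) and TUB6 (0.48) and the peptide RALFL32 (0.91). Each of COR47, CYP71B34, CYP71B6, TUB1, TUB6 and RALFL32 lost its call without replicate 1 of the mutant (adjusted p = 0.077, 0.12, 0.20, 0.071, 0.16 and 0.077) and without other single arrays, as did CYP71B26 (0.075), while XERICO (0.059) and TBL39 (0.054) lost theirs without its replicate 2.

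Within the plastid genome, 6 of 13 ribosomal protein genes fell in the mutant, and 5 or 6 of them did on leaving out any 1 array. Besides rpl22 and rpl14 these were rps3 (-1.47), rpl36 (-1.36), rps15 (-1.04) and rpl32 (-0.69), of which rpl32 lost its call without Ler replicate 2 (adjusted p = 0.066) or replicate 1 of the mutant (0.095). Of 4 RNA polymerase genes rpoA (-1.05) and rpoB (-0.68) were called lower, but rpoA had a signal of 1154 ± 706 in Ler and a change of -0.39 (adjusted p = 0.24) without Ler replicate 2, and rpoB lost its call without any 1 of the Ler or mutant arrays (up to 0.17). Of 27 genes of the photosystems, the cytochrome b6f complex and rbcL, none fell and rbcL rose (0.60), which was not called without Ler replicate 2 (adjusted p = 0.13) or replicate 1 of the mutant (0.20). Of 9 NDH genes 3 fell, of which none was called without Ler replicate 1 or either mutant array, and none of 6 ATP synthase genes was called. Of 7 other plastid genes 2 were called lower, accD (-0.74, adjusted p = 0.011) and ycf3 (-0.58, adjusted p = 0.043). Neither call was kept throughout when each array was left out in turn. These classes were formed after the values were seen, and genes transcribed together are not independent. The 6 ribosomal protein calls therefore need not be separate changes. The search for runs of neighbouring genes covered nuclear chromosomes only, so whether these falls lie in a single plastid gene cluster was not tested.

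**Figure D1:**
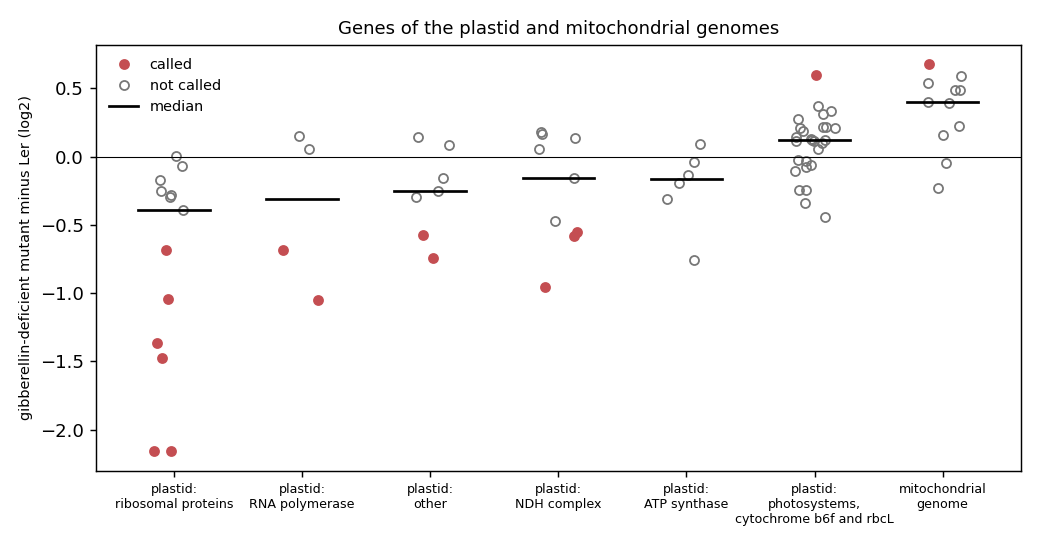
Log2 change of each plastid-encoded gene in the gibberellin-deficient mutant against Ler, by functional class, with 1 point per gene. The 13 ribosomal protein genes had a median of -0.39 and the 27 photosystem, cytochrome b6f and rbcL genes a median of 0.12.

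Differences between the mutant and Ler also lay in runs of neighbouring genes, by the gene order of assembly TAIR10.1. From AT1G01080 to AT1G02020, at the start of chromosome 1, 31 of 32 measured genes were higher in the mutant and 20 were called, with a median change of 0.66, or 1.58-fold. AN, TBL25 and UGT72B3 (1.04) lie in this run. UGT72B3 lost its call without any 1 of the Ler or mutant arrays (adjusted p up to 0.15). From AT1G63420 to AT1G64170, 20 of 22 measured genes were lower in the mutant and 9 were called, with a median of -0.62. Over the second run Ws and the de-etiolated mutant were also below Ler, with medians of -0.60 and -0.63. There the gibberellin-deficient mutant differed from Ws by a median of 0.0036 and from the de-etiolated mutant by -0.014. In this run Ler thus stood apart from all other groups. The ends of both runs were set after the data were seen. Without the probe sets of both runs, 1 for each measured named gene, 1435 probe sets changed, 601 higher and 834 lower. Any further probe sets of these genes, and unnamed ones in these intervals, were not taken out.

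**Figure D2:**
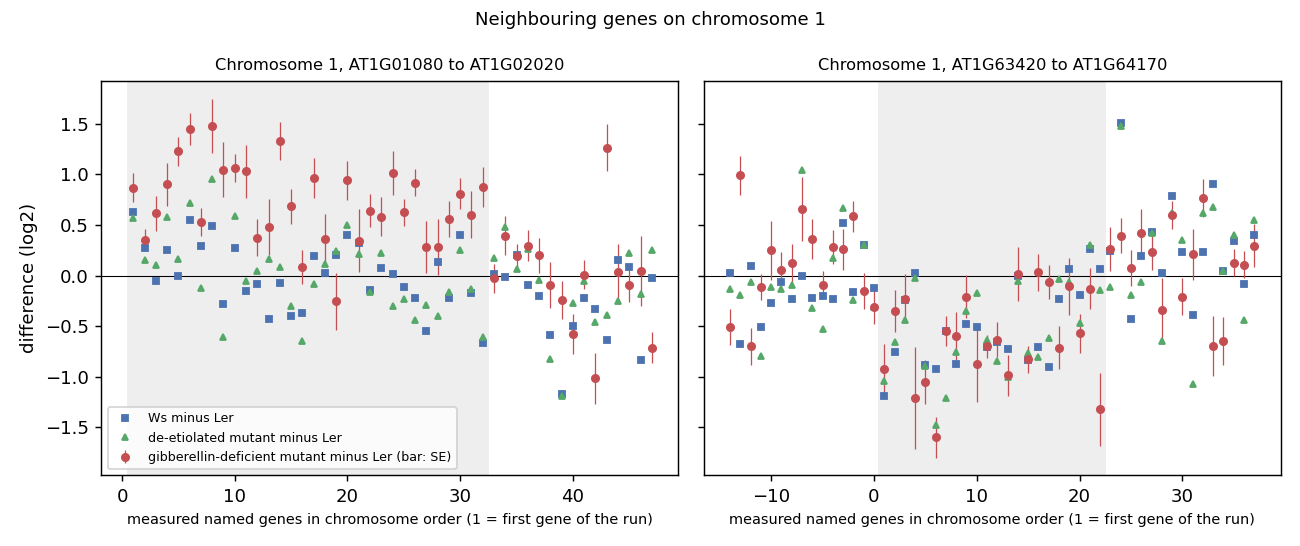
Log2 difference from Ler of neighbouring genes in and around the runs on chromosome 1, for the gibberellin-deficient mutant (bars, SE), Ws and the de-etiolated mutant. Medians per array relative to the mean of Ws and the de-etiolated mutant are not drawn. Over the first run they were 0.71 and 0.67 in the gibberellin-deficient mutant and -0.01 and -0.01 in Ler. Over the second run they were 0.53 and 0.71 in Ler and 0.13 and -0.05 in the gibberellin-deficient mutant.

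Leaving out a Ler or mutant array leaves 1 array in that group and lowers the power, so a smaller count by itself points to no particular array. The count of changed probe sets fell without each of these arrays. It was 528 without Ler replicate 1, 855 without Ler replicate 2, 440 without replicate 1 of the mutant and 550 without its replicate 2.

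The comparison of the de-etiolated mutant with the mean of Ws and Ler asked which transcripts set this mutant apart. Its mutation and its Col accession cannot be told apart here, and this holds for every difference of the comparison. The older actin control ratio in the mutant was like that of Ws and below that of Ler, and its 25S rRNA signal was above that of all wild-type arrays. Of 19 listed genes of flavonoid and anthocyanin synthesis only 3 were measured, and all 3 were lower in the mutant. Of 7 measured xyloglucan endotransglucosylases 4 were lower, none of them called against Ws alone, and the call of this list was lost with an estimated correlation (adjusted p = 0.19). Signal of DFR, which makes the precursors of anthocyanins, was 40.7 ± 3.88 in the mutant, 131 ± 8.36 in Ws and 402 ± 184 in Ler, a log2 change of -2.38 (SE 0.21, adjusted p = 5.12e-05). AT3G16670 was higher by 4.48 (SE 0.28), at 1228 ± 159 in the mutant, 65.0 ± 4.28 in Ws and 46.8 ± 31.6 in Ler. In all 1501 probe sets changed, 744 higher and 757 lower, of which 335 at least 2-fold (160 higher and 175 lower).

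The flavonoid and anthocyanin list had 3 measured members, too few for camera, and all 3 fell. They were DFR, the anthocyanin glycosyltransferase UF3GT (-2.42) and AT4G14090, an anthocyanin glucosyltransferase (-2.60). DFR and AT4G14090 were also lower against each wild type alone, by -1.62 and -1.70 against Ws and by -3.14 and -3.50 against Ler. UF3GT was lower against Ler (-3.05), and its change against Ws of -1.78 did not pass the test (adjusted p = 0.0505). AT5MAT, which adds malonyl groups to anthocyanins, fell as well (-1.58). DFR (-1.52) and AT4G14090 (-1.79) were also lower in Ws than in Ler, and UF3GT had a change of -1.27 there (adjusted p = 0.11), which passed without replicate 1 (0.0061) or replicate 2 (0.0069) of the de-etiolated mutant.

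Xyloglucan endotransglucosylases were shifted downward (camera, adjusted p = 0.0037), and with an estimated correlation they were not called (adjusted p = 0.19). Of 7 measured members 4 fell, XTH16 (-0.70), XTH33 (-0.93), EXGT-A3 (-0.49) and XTH18 (-0.71), and 5 were lower and 1 higher when adjusted over the list alone. XTH26, from an added list, fell too (-1.12). Its change of -0.87 between Ws and Ler lost its call without any 1 of 7 arrays, and was -0.53 (adjusted p = 0.30) without Ws replicate 2. Expansins were not shifted as a list (adjusted p = 0.17), although 2 of 9 rose, of which EXPA8 rose by 1.12. EXPA8 and XTH16, which went opposite ways, were the only measured members of the list of genes known to be induced by brassinosteroids. No brassinosteroid feedback gene was named by a probe set. EXO, a brassinosteroid-responsive gene of an added list, fell (-1.04). Against Ws alone none of the 4 genes XTH16, XTH33, EXGT-A3 and XTH18, nor XTH26 or EXO, was called (adjusted p = 0.0591 to 0.295). Of the glucosinolate genes, AOP3 (-2.24) and BCAT4 (-0.64) were lower than the mean of both wild types. Neither was called against Ws, where AOP3 had a change of 0.58 (adjusted p = 0.53) and BCAT4 of -0.54 (adjusted p = 0.17), and the fall of AOP3 rested on its high level in Ler. Without replicate 1 of the mutant the calls of EXPA8 (adjusted p = 0.10), EXGT-A3 (0.10), XTH18 (0.12) and BCAT4 (0.25) were lost, and without its replicate 2 those of XTH33 (0.057), EXO (0.067), EXGT-A3 (0.11) and XTH18 (0.18).

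Among genes with a symbol, the largest rises were in P1R1 (1.68), CP5 (1.26), SIS (1.14), the methionine sulfoxide reductases MSRB6 (1.14) and MSRB5 (0.99), EXPA8, bHLH121 (1.11) and the sucrose phosphate synthase ATSPS4F (0.98). The falls were ranked among genes whose arrays did not overlap between the groups, which left out AOP3. After the anthocyanin genes, the largest were in CYP71B23 (-1.82), APL3 of starch synthesis (-1.21), RING1 (-1.20), the pyruvate phosphate dikinase PPDK (-1.17) and ATPMEPCRB (-1.17). By locus tag, AT3G28320 (2.97), AT4G33666 (2.54), AT3G16660 (2.41), AT5G01740 (2.41), AT1G47400 (2.18), AT3G03270 (2.07) and AT3G62550 (2.06) rose after AT3G16670. Signal of AT3G03270 was 1227 and 504 in the mutant's arrays, 424 and 423 in Ws, and 81.2 and 79.3 in Ler, and its change against Ws was 0.89 (adjusted p = 0.16). AT1G70810 (-2.58), AT1G65500 (-2.50), AT1G14210 (-2.25), the lectin AT3G16530 (-2.12), AT1G70880 (-1.91), AT1G51850 (-1.89) and AT1G43910 (-1.86) fell after AT4G14090. With a pseudocount of 50% of the median signal the changes of AT3G28320 (2.36), AT1G70810 (-1.82), AT1G70880 (-1.24) and AT1G51850 (-1.29) were smaller. Against Ws alone, bHLH121, MSRB5, ATSPS4F, UF3GT, CYP71B23, AT5MAT, APL3, RING1, ATPMEPCRB, AT3G03270, AT3G62550, AT1G70810, AT1G65500, AT1G70880 and AT1G43910 were not called (adjusted p = 0.0505 to 0.34). No list added after the annotation was read was called by camera in this comparison. Single members changed, among them bHLH121 and PYE (0.93) of iron homeostasis, NdhS (0.80), NdhL (0.71), LHCB4.2 (0.62) and PSB27 (0.50) of photosynthesis and the sugar transporters SWEET11 (0.88), SWEET2 (0.80) and SWEET1 (-0.68). Like bHLH121, the other 8 of these were not called against Ws alone (adjusted p = 0.0834 to 0.232). Without replicate 1 of the mutant APL3 (adjusted p = 0.062), RING1 (0.057), AT1G70810 (0.16), AT1G43910 (0.16), LHCB4.2 (0.092), NdhL (0.078), SWEET11 (0.054), SWEET1 (0.062) and bHLH121 (0.052) were not called. Without its replicate 2 CYP71B23 (0.066), AT3G62550 (0.074), ATSPS4F (0.10), PYE (0.16), NdhL (0.15) and AT1G43910 (0.084) were not.

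Against Ws alone 306 probe sets changed, and 244 changed the same way against both wild types, 150 higher and 94 lower in the mutant. The count against the mean was 895 without Ws replicate 2, 621 without replicate 1 of the mutant, 923 without its replicate 2 and 966 without Ler replicate 2. The count changed the same way also fell without either Ws array, replicate 1 of the mutant or Ler replicate 2. Its excess of higher calls was absent without Ws replicate 1 or replicate 1 of the mutant. That excess stayed without Ws replicate 2 or Ler replicate 2.

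**Figure D3:**
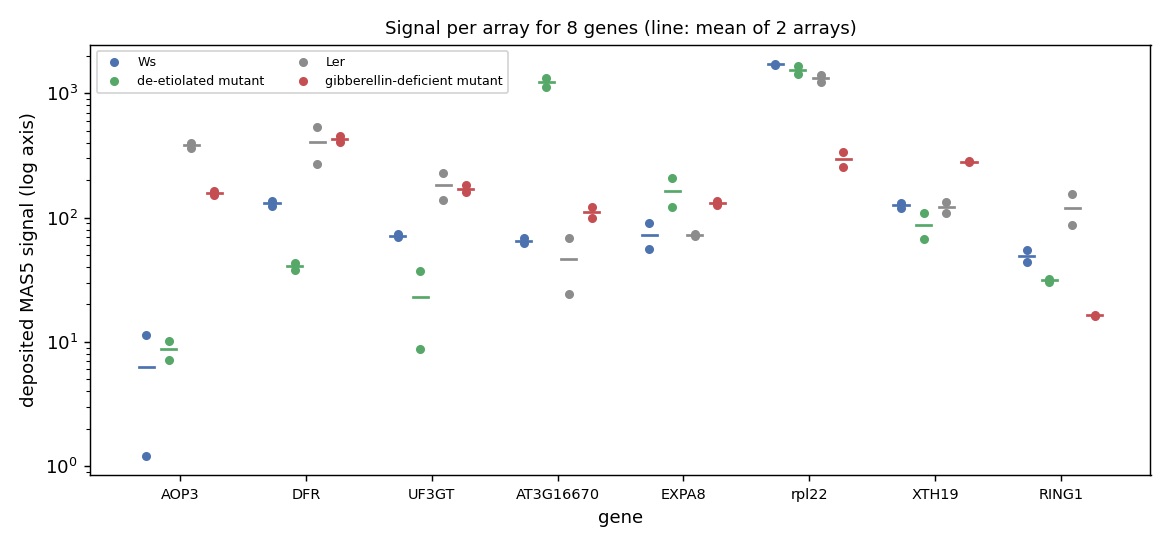
Signal of 8 genes in each of the 8 arrays on a log axis, with 1 point per array, by group. DFR was lowest in the de-etiolated mutant, and rpl22 was 297.5 ± 58.9 in the gibberellin-deficient mutant against 1328 ± 123 in Ler.

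The comparison of Ws with Ler gave the size of an accession difference measured in the same way. AOP3 and AT2G25450, which both act on glucosinolate side chains, differed in opposite directions. Signal of AOP3, which modifies the side chain of methionine-derived glucosinolates, was 399 and 366 in the Ler arrays, 162 and 151 in the gibberellin-deficient mutant, and 1.21, 11.3, 10.3 and 7.13 in the arrays of Ws and the de-etiolated mutant. Its log2 change was -5.64, and -6.37 or -4.28 with a pseudocount of 2% or 50% of the median signal. AT2G25450, a dioxygenase of glucosinolate side chains, went the other way (6.60, and 7.14 or 5.29 with these pseudocounts), at 774 ± 176 in Ws and 5.20 ± 2.83 in Ler. With signals this low in 1 group, the size of a log2 change depended on the pseudocount. The glucosinolate list had 2 measured members, too few for a test, and BCAT4 had a change of -0.21 (adjusted p = 0.63). AOP3 was the only label check gene named by a probe set. In all 794 probe sets changed, 370 higher and 424 lower in Ws, of which 377 at least 2-fold (162 higher and 215 lower).

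The proline iminopeptidase PIP (2.66), ACLA-2, a subunit of ATP-citrate lyase (1.96), the subtilase SBT4.12 (1.87), LUL1 (1.66), KELP (1.36), plastid ccsA (1.28), the glutathione transferase GSTU16 (1.22) and NET4B (1.11) were higher in Ws. The lectin JAL33 (-3.49), the histone HTB11 (-3.49), ECS1 (-2.81), CXE20 (-2.27), DI21 (-2.09), ALDH6B2 (-1.81) and the osmotin OSM34 (-1.69) were lower in Ws. By locus tag, AT2G25510 (5.70), AT3G44430 (5.14), AT2G15560 (4.31), AT5G23830 (4.02), AT5G38020 (3.9), AT2G01090 (3.74) and AT5G45500 (3.61) were higher. AT4G33720 (-3.70), AT1G73490 (-3.56), AT5G55450 (-3.41), AT2G40010 (-3.31), AT3G47250 (-3.25), AT5G47980 (-3.25), AT1G65500 (-3.09) and AT2G21045 (-2.96) were lower. With a pseudocount of 50% of the median signal the changes of AT3G44430 (3.58), AT5G23830 (2.85), AT2G01090 (2.58), AT2G15560 (3.26), AT5G45500 (2.79), AT4G33720 (-2.59), AT3G47250 (-2.48), AT2G40010 (-2.65), HTB11 (-2.77) and CXE20 (-1.58) were smaller. Neither expansins (adjusted p = 0.18) nor xyloglucan endotransglucosylases (adjusted p = 0.83) were shifted. Nuclear photosynthesis genes, an added list, were shifted upward in Ws (camera, adjusted p = 0.018) with none of 19 members called, as were plastid-encoded genes (adjusted p = 0.040) with 2 higher and 3 lower of 66. With an estimated correlation both had an adjusted p = 0.74. Without Ws replicate 1 the calls of GSTU16 (adjusted p = 0.14), KELP (0.12), LUL1 (0.10), NET4B (0.11) and ccsA (0.16) were lost, as were those of KELP (0.23) and ccsA (0.24) without Ler replicate 2 and of NET4B (0.17) and GSTU16 (0.098) without Ler replicate 1.

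Probe sets were made on the Col sequence, so sequence differences of Ws or Ler can lower a signal without a change in transcript. The share of higher calls moved from 46.6% to 60.9% (469 higher and 301 lower) when each array was scaled to the same median. The older actin control ratio, given above, also separated Ler from Ws. The count was 340 without Ws replicate 1, 484 without Ws replicate 2, 462 without Ler replicate 1 and 389 without Ler replicate 2.

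**Figure D4:**
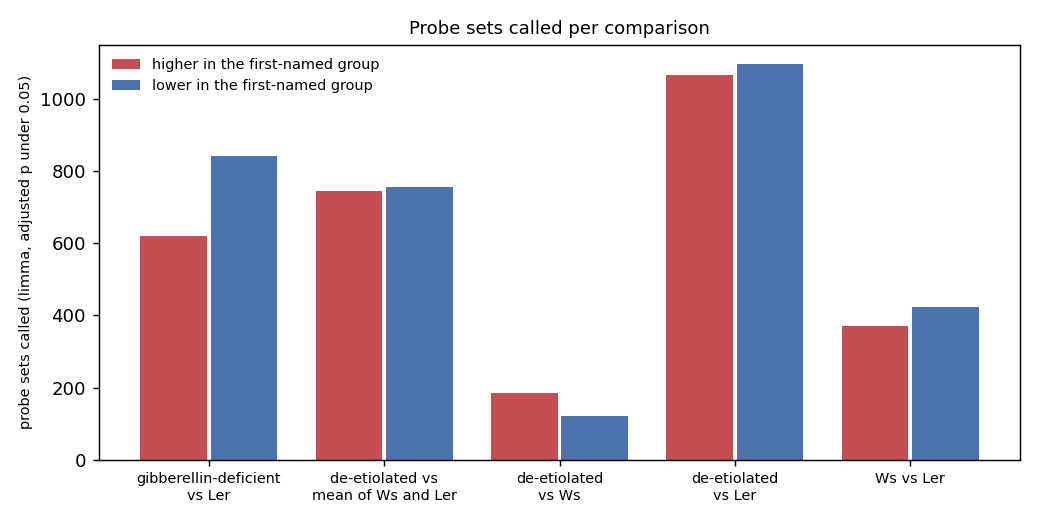
Number of probe sets higher and lower in each comparison at an adjusted p under 0.05. The gibberellin-deficient mutant against Ler had 621 higher and 843 lower, and Ws against Ler had 370 higher and 424 lower.

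The changes of both mutants were then set side by side, the gibberellin-deficient mutant against Ler and the de-etiolated mutant against Ws, which share no array. Across 13648 probe sets, which are not independent replicates, Pearson's r was 0.249 and Spearman's rho 0.238. Of the probe sets called in both, 36 were higher in both mutants where independent lists would give 8.37, 34 were lower in both (7.54) and 24 went opposite ways (16.9). With Ler as the control of both, r was 0.375. Unchanged groups simulated against shared Ler arrays gave 0.500. Equal noise around a shared control fixes that value, so it cannot be set against the observed r. The covariance was 0.0990 against a simulated 0.0233. The simulation held array noise only, and any lasting trait of the Ler samples would add to the covariance. The excess therefore cannot show that the mutants share changes. EXPA8, which rose in the de-etiolated mutant, had a change of 0.82 in the gibberellin-deficient mutant (adjusted p = 0.060), which passed without any 1 array of Ws or the de-etiolated mutant (0.030 to 0.041). RING1, CYP71B23 and ATPMEPCRB, lower in the gibberellin-deficient mutant, were not called in the de-etiolated mutant against Ws (adjusted p = 0.27, 0.14 and 0.17). The 25S rRNA control was higher in all 4 mutant arrays (39.6 to 108) than in all 4 wild-type arrays (22.2 to 32.0). The correlation was 0.151 without Ws replicate 2.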

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

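All alternatives here were planned except the counts without the runs of neighbouring genes, chosen after the runs were seen. Of 3367 alternative values of 190 named results, 2957 kept their direction and side of the threshold, 393 fell below it (273 of them on leaving out an array, where the lone array of a group is assumed to vary like the others, 14 in fits on the compared groups alone), 17 passed it newly and 0 reversed. Of the 393, another 105 were lost under other normalizations, pseudocounts, filters, trend settings or choices of probe sets, and 1 under the replicate block. With no filter on dim probe sets, 967 probe sets changed in the de-etiolated mutant against the mean of both wild types, 106 against each, and the correlation between the mutants was 0.163. Without the mean-variance trend, 90 changed against each. Asking for 2-fold left 498 (gibberellin-deficient mutant), 335 (de-etiolated mutant, mean), 106 (against each) and 377 (Ws against Ler), by its construction. List counts here cover the 2 testable lists fixed beforehand, not the added ones. With the lowest 60% left out, 2 were called in the gibberellin-deficient mutant. With the estimated correlation, 0 of them were called in it and 0 in the de-etiolated mutant, where the preset one called 1 each. Ws alone as the control gave 306, probe sets with p over 0.05 between Ws and Ler gave 617, and Ler as the control of both gave a correlation of 0.375. Leaving out each array in turn gave 440 to 1606 (gibberellin-deficient mutant), 621 to 1418 (de-etiolated mutant, mean), 57 to 289 (against each), 340 to 843 (Ws against Ler), 0 to 1 lists for Ws against Ler (1 without Ws replicate 2), 1 of these lists for each mutant in every case, and correlations of 0.151 to 0.307. Apart from fewer samples or probe sets tested, the cause was not tested. With the replicate block, 1579, 1700, 332 and 882 probe sets changed and no call of these lists changed. Deviations of same-lettered arrays correlated by -0.03 to 0.14, so the letters were not taken as pairs. Signal near background limits dim genes such as AOP3 in Ws.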

Other observations

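The tests of the runs, of the low-oxygen genes and of the falls in the de-etiolated mutant were chosen after the result was seen, and those of neighbouring pairs and of the share of rises in that mutant were set before it.

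A list of genes known to respond to low oxygen was written from textbook knowledge after the largest changes had been seen, and 23 of its genes were measured. In the gibberellin-deficient mutant against Ler 11 rose, all of them among the genes seen first, so this count and the list's median of 1.06 rest on genes chosen for the pattern. They included AT5G10040 (2.25), AT4G39675 (2.22), AT1G33055 (1.79), AT2G17850 (1.78) and AT4G27450 (1.63), the last at 1933 and 1912 in the mutant's arrays against 915 and 420 in those of Ler. Of the 10 members not looked at before, 0 were called higher and AT5G27760 was called lower (-0.72, adjusted p = 0.0086), a call lost without Ler replicate 2 (0.057) or replicate 2 of the mutant (0.088). The call of AT4G27450 was lost without Ler replicate 2 (0.099) or either mutant array. Over the whole list the median was 0.54 in the de-etiolated mutant against both wild types and -0.11 between Ws and Ler.

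A set of 59 probe sets lay at least 4-fold apart between Ler and both Ws and the de-etiolated mutant. The gibberellin-deficient mutant lay nearer to Ler for 45 of them (76.3%), and no expected share for a Ler background was computed. Of the other 14, 11 were higher in Ler and 3 lower. Of 11 measured mitochondrial genes, cox1 rose in this mutant (0.68) and in the de-etiolated mutant against the mean of both wild types (0.62, adjusted p = 0.039), calls that were lost without replicate 1 of the mutant concerned (adjusted p = 0.37 and 0.24) and without other single arrays. None fell in the gibberellin-deficient mutant.

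The runs on chromosome 1 came from a search in which no shuffle gave a window as large as the largest in the gibberellin-deficient mutant against Ler (a median of 0.96, where 95% of shuffles stayed under 0.58). A segment of other sequence in the mutant line predicted an excess of neighbouring pairs called the same way, and 54 were found where shuffles gave a median of 38 and a 95% limit of 48, but without the runs 39 were found (limit 45). Ws against Ler (32, limit 17) and the de-etiolated mutant against Ler (112, limit 100), which share the Ler arrays, had an excess too. The de-etiolated mutant against Ws (4, where shuffles gave a median of 1 and a limit of 4) lay at its limit and not above it. For the first run, mismatch of Ler sequence is argued against, since Ws and the de-etiolated mutant exceeded Ler by medians of at most 0.0644, while an extra copy in the mutant and other causes that raise neighbouring genes together cannot be told apart: at least 93.3% of the 15 genes chosen in replicate 1 were higher in the mutant in replicate 2, but the run was known from both replicates, any lasting rise would pass, and no DNA was measured. For the second run mismatch is argued against by a median of -0.63 in the de-etiolated mutant against Ler, and a chance arrangement by the shuffles, since its genes from AT1G63420 to AT1G63850 held the largest windows of Ws against Ler (-0.71, with 0 of 1000 shuffles as large) and of the de-etiolated mutant against Ler (-0.75, with 3 of 1000), which share the Ler arrays. An extra copy in Ler stays open for it, because the window chosen in replicate 1 lay elsewhere (AT1G54320 to AT1G54820, with 60% of genes higher in Ler in replicate 2) and says nothing about this run, and a first test on the runs' own genes, which gave at least 96.9% and 81.8% and had counted for an extra copy in both, was dropped since those genes had been picked for the pattern.

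In the de-etiolated mutant, mismatch of Ws and Ler RNA to probes made on the Col sequence could raise its signals against both. Of 13 probe sets at least 4-fold from both wild types in the same direction, 9 were higher in the mutant (69.2%, exact binomial interval 38.6% to 90.9%), so for these 9 mismatch, accession and mutation cannot be told apart. Mismatch of the wild types would not give the 4 that were lower.

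For the low-oxygen genes, a shift of the group is consistent with the 10 members whose values had not been looked at, with a median of 0.53 at percentile 99.98 of 10000 random lists matched on mean signal. Of these 10, 9 had a change above 0, with none called higher. The same members lay at percentile 99.96 in the de-etiolated mutant. The random lists held unrelated genes, while genes of a shared response can move together between arrays. Both percentiles therefore overstate how unusual these medians are. Growth or sampling differences between single samples could also give such a pattern, since the arrays of the de-etiolated mutant differed by a median of 1.04 over the list, against 0.37 within Ler and 0.22 within the gibberellin-deficient mutant. With 2 arrays per group, these differences and an effect of the mutation cannot be told apart.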
